A study of Oryza sativa with 5 samples.

How the data were processed

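ChIP-seq values were taken from 12 deposited region tables, 1 per chromosome, for 5 libraries with 1 library per group. Leaves were cross-linked and chromatin was sheared to 100 to 300 bp, per the labels' protocols. Reads were processed with Bowtie and HOMER on the build IRGSP-1.0, per the submitters' processing notes. The versions and the step each tool did are not given in the sources used here. The deposited tables hold a read count per region and library, not scaled, per the file headers. The authors also give RPM, counts scaled to mapped reads, per the file headers, and 100.0% of those values equalled the count over the mapped reads in the last line of each table. Counts were used throughout and RPM only for that check. The tables hold 8 further columns of values per table, of 4 histone-mark libraries, which were not used in any step. Regions listed from those libraries were kept as places to count reads of the 5 libraries.

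Of 80469 lines, 12510 (15.5%) hold no values here, which leaves 67959 named regions. The regions are listed library by library, and a check of the values showed that counts and regions on one line do not belong together. Region names run in the order tagged anti-myc, transgenic anti-Pol II, transgenic histone marks and then the same lists of the nontransgenic plant, while counts run in the sorted order of the library names. Counts were moved to the regions by this order, which left 57347 regions with both. This pairing was chosen after the data were seen, and no source used here states it. The correlation of region length with summed reads was 0.626 to 0.712 by chromosome after pairing and -0.135 to 0.015 on the deposited lines. Length gave no such correlation in the short lists of anti-myc peaks and of nontransgenic anti-Pol II peaks. The transgenic anti-Pol II peaks gave 0.484, against 0.129 on the deposited lines, but a shift by 1 line still gave 0.389 or 0.405 there. Over all regions, a shift by 1 line gave 0.166 or 0.164. With the tagged anti-myc and transgenic anti-Pol II lists swapped, 23 of 72 short regions with dinucleotide runs were at least 4-fold over input, against 75 of 75. The order of the anti-myc and anti-Pol II lists of the nontransgenic plant, with 36 and 17 regions, could not be settled this way, since 0 of their short regions hold such runs.

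Overlapping regions hold separate reads, as when each read is given at random to 1 of the regions that contain it. This was also found from the values and is stated in no source used here. With each base divided by the number of listed regions over it, the correlation of length with reads was 0.843, against 0.666. Ratios between libraries are not shifted by it, but a region's depth is. Gene values are sums over all regions listed for the gene. Regions without values here take reads as well and are missing from sums.

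Ratios are counts over mapped reads. A count of 0 was set to a floor of 3 reads, and ratios against it are written as at least that fold, for the observed counts. Intervals are Clopper-Pearson intervals of the split of 2 counts at a level of 95%, and reads carry no molecular identifiers, so intervals and floors cover counting error only. A Roc10-myc region was called at a ratio of at least 4 with at least 10 reads. Pol II was called higher or lower at 2-fold with at least 20 reads over both libraries. Over input, the thresholds were 2-fold for Pol II and 4-fold for anti-myc, with at least 10 reads. The number of calls that counting error alone gives was computed from the binomial split of each region's summed count. List medians are given as percentiles among 10000 random lists matched in 20 bins of Pol II reads. The motif was compared with 1000 base shuffles. These settings and the lists were fixed before the data were examined, apart from the minimum over input, the floor and the bins.

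Named binding regions are the 15 with the highest lower limit of the anti-myc ratio in genes with a functional description. Named Pol II genes are the 12 highest and 12 lowest by the interval limit nearest to 1 among genes with at least 20 reads and a functional description, and up to 3 members of each list past 2-fold. For Pol II over input the 10 highest by the lower limit are named. Roc genes, the PGD1-like gene and peroxidase genes are named whether or not they pass, with the extremes and keyword exceptions given for peroxidases. Called regions outside the 15, the 3 Pol II genes without a described function, Os04t0449200-01, the monolignol genes, Os02t0151300-01 and the fifth lower peroxidase were chosen for naming after their values were seen. Gene names come only from the descriptions in the tables, since the reference table pairs no identifiers of the kind used there.

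The tables list a feature for 26.0% of regions and no strand, so promoters could not be formed. Location is given as listed, and genes near a called region are those with a listed feature within 2000 bp, where the plan was a window around the start. Dinucleotide runs of at least 40 bp and high copy, an input density of at least 4 times the genome mean with overlapping regions allowed for, were defined after the data were seen. Alternatives were median-of-ratios scaling, other thresholds, minimums and controls, subtraction of input, and matching on length. Added after the data were seen were other pairings, leaving out runs, high-copy regions or the peaks of the transgenic anti-Pol II library, and pooling overlapping regions.

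The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Calls and intervals were tested on simulated data with 200 changed regions among 57347. The changed regions were drawn only from deeper regions, with summed reads well above the minimums for a call. Intervals covered the true ratio of 4-fold Roc10-myc regions in 95.0% of cases and of 2-fold Pol II regions in 98.0%. Of 200 random lists of 20 genes, 3.50% fell outside the middle 95%.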

Results

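Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on leaves of 2-week-old rice plants of the cultivar Ilmi. One genotype was nontransgenic and the other carried PGD1::6xmyc-Roc10, a transgene that makes Roc10, a homeodomain-leucine zipper transcription factor, with a myc tag. The 5 libraries were 1 nontransgenic input, 1 anti-myc and 1 anti-Pol II library of the nontransgenic plant, and 1 anti-myc and 1 anti-Pol II library of the transgenic plant. Each group held 1 library, so no difference has a replicate check and no test between conditions was possible. The intervals below are exact conditional binomial 95% intervals and cover counting error only.

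The mapped reads numbered 17537817 for the input, 9578225 for nontransgenic anti-myc, 8526788 for nontransgenic anti-Pol II, 5769566 for transgenic anti-myc and 9475795 for transgenic anti-Pol II. The median region held 38 input reads, 22 and 20 reads in the nontransgenic anti-myc and anti-Pol II libraries, and 13 and 20 in the transgenic ones. The values below cover 57347 regions at 29349 distinct loci and 62.4 Mb of the genome build IRGSP-1.0. Most regions are listed from histone-mark libraries whose own values were not used here, so the regions are a sample of marked chromatin and not of the whole genome.

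The read counts stand on other lines than the regions they belong to, and were paired with them by library order. On the deposited lines, region length and summed reads had a Spearman correlation across regions of -0.041, and after pairing by library order the correlation was 0.666. Regions of up to 400 bp with a run of a CA/GT or GA/TC dinucleotide repeat of 40 bp or more gave a check by sequence. All 75 of them held at least 4-fold more ChIP reads than input after pairing, against 0 of 98 on the deposited lines. Reads per kb also depended on how many listed regions lay over the same bases. Where 1, 2, 3 or 4 regions covered each base, the median region held 40.7, 24.1, 14.6 and 9.89 input reads per kb. Among 2027 pairs of regions that shared at least 97% of their span, counts were equal in only 5.59% of comparisons, and their scaled difference had a median of 0.707, where independent counts give 0.674. A region's count was therefore read as a share of the reads at its place, and the reads of overlapping regions were summed per gene.

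**Figure D1:**
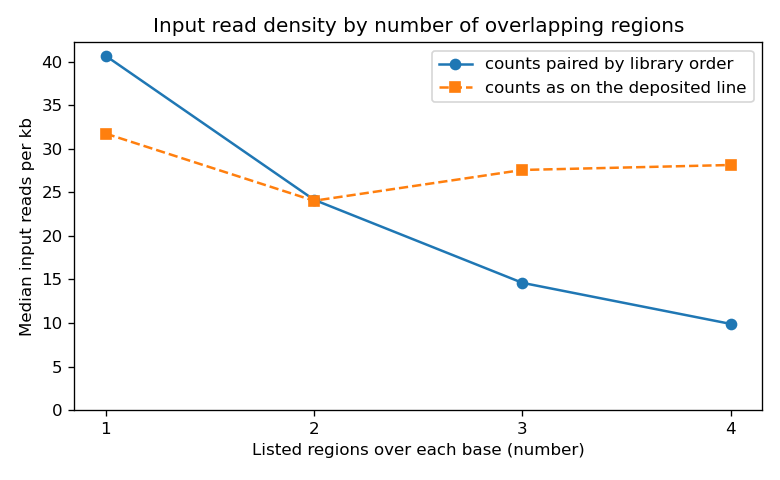
Median input reads per kb (vertical axis) against the number of listed regions over each base (horizontal axis), for counts paired by library order and for counts as on the deposited line. Paired by library order, the density falls from 40.7 reads per kb under 1 region to 9.89 under 4.

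The first comparison asks where the tagged Roc10 protein lies on the genome, with anti-myc reads of the untagged plant as the control. Regions with at least 4-fold more anti-myc reads in the tagged plant, and at least 10 reads there, numbered 48, where counting error alone gives 34.3. The clearest region in a gene lay in the coding sequence of Os03t0721200-01, an Armadillo-like helical domain protein (chromosome 3, 29260969 to 29261178), with 14 reads against 2 and a ratio of 11.6 (2.67 to 105). A region in the 3′ UTR of the leucine rich repeat gene Os01t0515300-01 held 11 reads against 2, a ratio of 9.13 (1.99 to 84.8). A region in the coding sequence of Os06t0658000-00, similar to an AP2-EREBP transcription factor, held 12 reads against 3, a ratio of 6.64 (1.79 to 36.7). The cell wall invertase gene Os04t0664800-00 had a called region in its 5′ UTR with 13 reads against 5, a ratio of 4.32 (1.44 to 15.5).

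These 4 regions overlapped no other listed region. At other named genes the excess was lower once overlapping regions were pooled. The pooled counts still include the reads by which each region was called, so a pooled interval above 1 is no separate evidence. The protein kinase gene Os01t0364400-00 had 18 reads against 6 in its called region, a ratio of 4.98 (1.89 to 15.3). Pooled, it had 22 against 19, a ratio of 1.92 (0.993 to 3.76), so the added reads were mostly from the untagged plant. The C6HC zinc finger gene Os03t0625800-01 had 33 reads against 12 in a region with a dinucleotide run of 48 bp and 0 input reads, a ratio of 4.57 (2.30 to 9.71), and a pooled ratio of 1.61 (1.26 to 2.06). The proline-rich protein gene Os10t0149100-00 had 11 reads against 3 in its 5′ UTR and a pooled ratio of 1.39 (1.07 to 1.81). Os02t0570400-01, similar to ent-kaurene synthase 1A, had 15 reads against 6 in its called region. Pooled, it had 23 against 15, a ratio of 2.55 (1.27 to 5.25). The cupredoxin gene Os06t0681200-01 and the exonuclease gene Os01t0299700-01 had pooled ratios with intervals of 0.741 to 2.11 and 0.835 to 1.87.

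A further 8 named regions were above the control but under 4-fold, and each carried a dinucleotide run of 40 bp or more. The median anti-myc ratio over all 75 regions of up to 400 bp with such runs was 2.01. Os01t0354700-00, in a longer region of 1005 bp, and Os02t0257500-00 had lower limits above that median. The intervals of the others of the 8 included it, so their ratios do not set them apart as single sites. All 8 were chosen by their lower limits, so a high limit is no separate evidence. Os01t0354700-00, a Clp1 domain gene of pre-mRNA cleavage, held 127 reads against 73, a ratio of 2.89 (2.15 to 3.91). Os02t0257500-00, similar to a DNA binding protein, held 183 against 117, a ratio of 2.60 (2.05 to 3.30). The ratio was 2.35 at the 5′ UTR of the histidine-containing phosphotransfer gene Os08t0557700-01 and 2.83 at the 5′ UTR of Os02t0557200-01, similar to Auxin response factor 1. It was 2.03 at the 5′ UTR of the proteasome gene Os04t0485000-01 (RPN7), 2.31 at the glutamate receptor gene Os06t0246600-01, 2.72 at Os01t0633200-01 and 2.81 at Os08t0240600-00. A region of the calcium ATPase gene Os02t0176700-00, with a shorter run of 26 bp, held 986 reads against 833, a ratio of 1.97 (1.79 to 2.16). The F-box gene Os03t0652400-00, without such a run, had 8 reads against 1, a ratio of 13.3 (1.78 to 589), and was under the minimum of 10 reads.

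**Figure D2:**
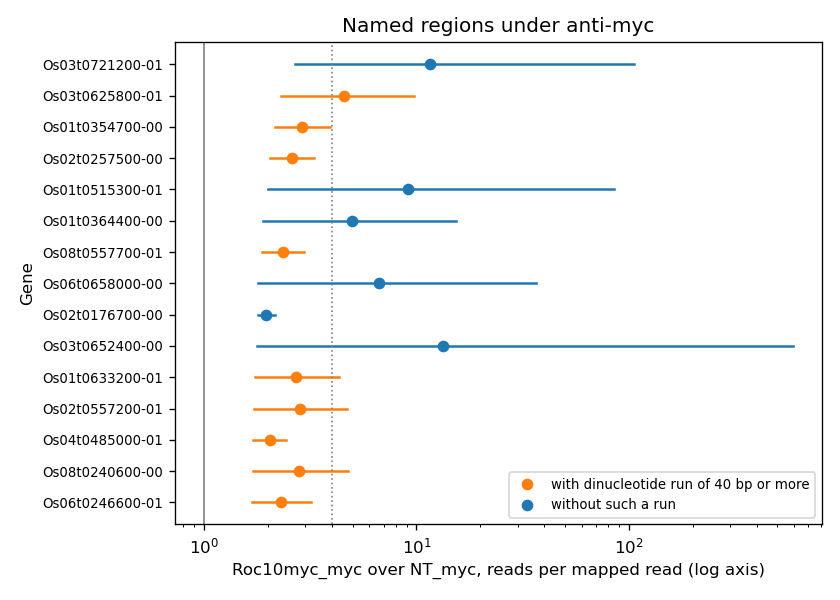
Ratio of reads per mapped read, tagged over untagged plant under anti-myc (horizontal log axis), with 95% counting intervals, for the 15 named genes (vertical axis). Orange points carry a dinucleotide run of 40 bp or more, and blue points do not, with Os03t0721200-01 at 11.6.

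Of the 48 called regions, 22 were among the 191 peaks listed for the tagged anti-myc library and 2 among the peaks of the transgenic anti-Pol II library. The other 24 were fewer than the 34.1 that counting error gives there. With reads pooled over overlapping regions, 24 loci passed, where counting error gives 3.83. These took in 19 of the 22 calls in tagged anti-myc peaks and 3 of the other 26. The 19 overlapped no other listed region, so pooling added no reads there and could not test them. In the other 3 calls in tagged anti-myc peaks it did add reads, and their pooled ratios were 1.61, 1.24 and 1.39. The peak list comes from the same library as the reads, so it is no separate evidence for them. The reverse comparison, at least 4-fold more reads in the untagged plant, gave 324 regions where counting error gives 204. The median ratio over all regions was 0.934. These counts use scaling by mapped reads. By median of ratios 57 regions were called, where counting error gives 29.3, so the excess depended on the scaling. The split by peak list and the reverse comparison were not counted at that scaling. Called regions held 10 to 33 reads in the tagged plant. Simulated 4-fold regions were called in 47.0% of cases and 8-fold regions in 99.5%. The simulated regions were drawn from places with more summed reads than nearly all called regions, so these shares do not hold at the depth of the calls.

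By coordinates alone, 10 of the 241 peaks listed for the tagged anti-myc library (4.15%) overlapped a peak of the untagged anti-myc library. Of the same 241 peaks, 77 (32.0%) overlapped a peak of the transgenic anti-Pol II library, and 15 overlapped a nontransgenic anti-Pol II peak. The untagged anti-myc list held 42 named peaks, and 10 of them (23.8%) overlapped a tagged anti-myc peak. It held 0 short regions with runs, though untagged anti-myc had a median of 38.5-fold over input in such regions. A low overlap is thus no sign of low background. Of 191 tagged anti-myc peaks with counts, 45 had runs and 36 were high-copy. Of 178 transgenic anti-Pol II peaks, 31 and 87 were, so shared peaks need not mean joint binding.

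The second comparison asks whether anti-Pol II reads differ between the genotypes. In the nontransgenic plant these reads had a median ratio over input of 1.06, so ratios between genotypes need not be ratios of Pol II occupancy. In its 1 region of 231 bp, Os07t0624700-01 (UMP/CMP kinase a) held 19 anti-Pol II reads in the transgenic plant against 1, a ratio of 17.1 (2.72 to 710). Os01t0705200-01, a late embryogenesis abundant repeat protein gene, held 22 against 5, a ratio of 3.96 (1.46 to 13.4). The lowest gene was Os10t0553600-00, an exostosin-like gene, with 7 reads against 30, a ratio of 0.210 (0.0778 to 0.488). The peroxidase 1-like gene Os07t0104233-00 held 13 against 34, a ratio of 0.344 (0.167 to 0.669).

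The single regions of Os07t0624700-01, Os01t0705200-01 and Os05t0413000-01 come from the peak list of the transgenic anti-Pol II library, so high reads in that library are no separate evidence there. In that list 37 regions were at least 2-fold higher and 0 lower, with a median ratio of 1.80. Other genes at the high end were the mitochondrial transcription termination factor-related Os05t0413000-01 at 3.78, the F-box gene Os09t0260000-01 at 2.78, the bromodomain gene Os02t0699900-01 and the methyltransferase gene Os09t0518900-01 both at 2.31, and the bindin-like Os01t0814100-01 at 2.28. A group of 5 genes carried high-copy sequence, defined by an input density of at least 4 times the genome mean. They were the cupredoxin gene Os07t0570550-00 at 2.04 (1.85 to 2.25), the ferredoxin gene Os03t0659200-01 at 1.92, the C2 domain gene Os04t0472900-01 at 1.74, the NB-ARC gene Os12t0198900-00 at 1.65 and Os01t0737700-00 at 2.08. Their anti-myc ratios between the genotypes were also above 1, at 1.72 (1.54 to 1.92), 1.58, 1.37, 1.49 (1.28 to 1.75) and 1.35 (0.952 to 1.92) in the same order, so higher ratios were not seen under anti-Pol II alone. At the low end were the peptidase M24 gene Os04t0321600-01 at 0.333 (0.189 to 0.566), Os04t0341900-00 at 0.225, the tetratricopeptide gene Os11t0266800-01 at 0.250 and the F-box gene Os08t0105100-01 at 0.420. The glycosyl transferase gene Os09t0432900-02 was at 0.478, Os04t0445400-01 at 0.346, the phospholipase C gene Os12t0562400-00 at 0.411 and the glutamyl-tRNA synthetase gene Os02t0121000-01, with 35 reads against 63, at 0.499916. By median of ratios Os09t0432900-02 and Os02t0121000-01 were at 0.508 and 0.531, no longer past 2-fold, and the ferredoxin gene Os03t0659200-01 was at 2.04, then past it. Os01t0272600-01, similar to Root determined nodulation 1, was at 0.409, and Os08t0174500-00, similar to Heading date 5, at 0.315.

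**Figure D3:**
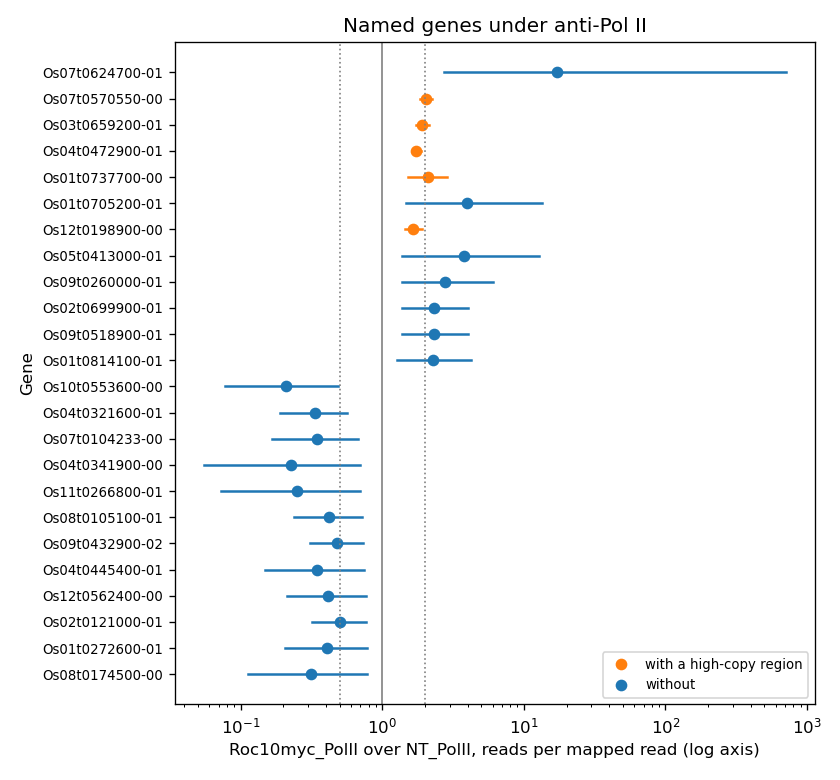
Ratio of reads per mapped read, transgenic over nontransgenic under anti-Pol II (horizontal log axis), with 95% counting intervals, for the 24 named genes (vertical axis). Orange points have a high-copy region and blue points do not, from 17.1 at Os07t0624700-01 to 0.210 at Os10t0553600-00.

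Genes without a described function were not ranked for naming, and some lay as far out: Os02t0613200-01 was at 5.06 (2.36 to 12.4), Os03t0104901-01 at 4.05 (1.64 to 11.99) and Os03t0762900-01 at 0.219 (0.0929 to 0.462). Of 7644 genes with at least 20 reads, 101 were at least 2-fold higher and 212 at least 2-fold lower, where counting error gives 138 and 126. Of 49957 regions, 739 were higher and 1480 lower, where counting error gives 1002 and 917. The split depended on the scaling. By median of ratios, 1066 regions were higher and 985 lower (52.0% higher, against 33.3%), where counting error gives 973 and 885. With the same scaling 150 genes were higher and 126 lower, where counting error gives 136 and 120. That scaling moved the Pol II ratio by 0.087 and the anti-myc ratio by 0.10 on the log2 scale. The median ratio over genes was 0.942. With at least 100 reads, 35 of 5031 regions were higher, 34 of them high-copy, and 0 were lower. Simulated 2-fold regions were called in 52.5% of cases and 3-fold regions in 91.5%. They were drawn only from regions well above the minimum of 20 reads, and shallower ones were not tested.

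Pol II over input in the nontransgenic plant asks what the Pol II antibody enriched. The strongest region lay in the calcium ATPase gene Os02t0176700-00 (chromosome 2, 4206293 to 4206434), with 754 reads against 1 in input, a ratio of 1551 (277 to 61334). Regions without an input read were compared with a floor of 3 reads, and their counting intervals reach lower than the ratio to that floor. Pol II reads were at least 138-fold higher at Os04t0485000-01 (RPN7), at least 98.7-fold higher at Os08t0557700-01 and at least 83.6-fold higher at Os03t0215200-00, similar to DROOPING LEAF, with lower interval limits of 111, 79.3 and 67.0. They were at least 67.9-fold higher at Os05t0165450-00 and at least 67.2-fold higher at Os06t0246600-01, the glutamate receptor gene. Regions with no listed gene included chromosome 10, 12014964 to 12015168, at least 148-fold, and chromosome 1, 17264116 to 17264228, at least 85.0-fold. On chromosome 7, 1244206 to 1244264 was at least 60.3-fold higher, and on chromosome 5, 5356186 to 5356300 held 148 reads against 1, a ratio of 304 (53.8 to 12104).

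At 2-fold, 1455 regions passed where counting error gives 604, and the median ratio was 1.06. At 4-fold, 184 regions at 123 loci passed where counting error gives 11.05, and 118 of them held a dinucleotide run of 40 bp or more.

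The anti-myc antibody in the untagged plant gives the background without a tag, and its strongest regions were the same 10. The calcium ATPase region held 886 anti-myc reads against 1 in input, a ratio of 1622 (290.4 to 64148), and Os04t0485000-01 was at least 133-fold above input. At 4-fold, 199 regions passed where counting error gives 10.4, and 114 of them held a dinucleotide run of 40 bp or more. Without regions with runs 85 passed. Of the 199, 147 were among the 184 Pol II regions, where independent lists would share 0.638. Both lists are ratios over the same input library, so regions with few input reads can pass in both and the lists are not independent. A set of 136 regions was at least 4-fold over input in all 4 ChIP libraries. Across 9717 regions with at least 200 reads, the ratio of anti-Pol II to anti-myc reads in one genotype had a Spearman correlation of -0.0030 with the same ratio in the other. The Pol II antibody thus gave no contrast to anti-myc over these regions that both genotypes shared. Regions are not independent replicates.

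Called regions lay in coding sequence in 12 of 48 cases (exact binomial interval 13.6% to 39.6%), in a 5′ UTR in 8.33% (2.32% to 19.98%) and in a 3′ UTR in 2.08%. All regions lay in coding sequence in 21.4% of cases and in a 5′ UTR in 3.05%. The peaks of the tagged anti-myc library lay in a 5′ UTR in 13.7% of cases (33 of 241, 9.62% to 18.7%), and those of the transgenic anti-Pol II library in 6.93% (4.01% to 11.004%). Of the 191 tagged anti-myc peaks with counts, 45 held dinucleotide runs, where the untagged plant was raised over input too. These peaks are also shorter, with a median of 140 bp against 1596 bp over all regions. The higher 5′ UTR share need not be a preference of Roc10. A feature was listed for only 26.0% of regions, so the rest cannot be read as intergenic.

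The L1 box TAAATG[CT]A, the textbook site of this protein family, occurred in 4 of the 48 called regions (8.33%; 2.32% to 19.98%), which is the 83.8th percentile among 1000 base shuffles of the motif. It occurred at 0.109 sites per kb in called regions and 0.0801 in 38291 regions not called that had at least 10 tagged anti-myc reads, which are longer and held it in 14.7% of cases. All 4 lie among the histone-mark regions, and 0 of the 22 called peaks of the tagged anti-myc library held the box (upper limit 15.4%). In the peaks of the tagged anti-myc library it occurred in 2 of 241, the 51.2nd percentile. The dimer core occurred in 0 of the 48, which allows a share of up to 7.40% by the exact interval.

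Genes within 2000 bp of a called region numbered 15 with enough Pol II reads, and their median Pol II ratio was 0.977. Most of the 15 lay by called histone-mark regions. Calls outside the transgenic peak lists numbered 24, where counting error gives 34.1, so the median says little about genes near Roc10 sites. That median was at the 68.5th percentile among 10000 random lists matched on Pol II reads, whose middle 95% ran from -0.32 to 0.13 on the log2 scale. Os01t0705200-01, the late embryogenesis abundant repeat gene, was the 1 gene at least 2-fold higher, and 0 were at least 2-fold lower. Its region and the called region beside it, with 21 Pol II reads against 5, are both peaks listed for the transgenic anti-Pol II library, so the higher Pol II is no separate evidence. The gene's own anti-myc ratio was 1.11 (0.392 to 2.94). The cell wall invertase gene Os04t0664800-00 had a ratio of 0.977 (0.601 to 1.59), and Os02t0151300-01, similar to cellulase, 1.03 (0.688 to 1.54).

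The study's title links Roc10 to lignin, so the genes of lignin formation were read as lists. Anti-Pol II reads were little set apart from input and anti-myc reads, so a flat list does not show unchanged transcription. Of 55 genes taken by the keyword peroxidase, 48 had enough Pol II reads, 0 were at least 2-fold higher and 5 at least 2-fold lower. Their median ratio was 0.956, at the 64.0th percentile among random lists. The 5 lower genes were Os07t0104233-00 at 0.344, Os04t0688200-01 at 0.318 (0.103 to 0.844), Os06t0490400-00 at 0.409 (0.173 to 0.900), Os04t0423800-01 at 0.485 (0.234 to 0.963) and Os04t0688600-01 at 0.485 (0.164 to 1.31). The highest were Os04t0689000-01 at 1.80 (0.836 to 4.11), Os07t0104100-01 at 1.60, and Os06t0306300-01 and Os04t0465100-01 both at 1.59 (0.773 to 3.42). The interval excluded 1 from above in 0 of the 48 and from below in 4. Of all 7644 genes with enough reads, 101 were at least 2-fold higher and 212 at least 2-fold lower. The lower genes are thus a larger share of the 48 than of all genes, on few genes, and this was not tested. The keyword also took 2 phosphatase genes with a haloperoxidase domain, Os02t0661800-01 at 1.58 and Os08t0127500-01 at 1.44. With median-of-ratios scaling 3 of the 48 were lower, since Os04t0423800-01 and Os04t0688600-01 were then both at 0.515, and 126 of all 7644 genes were lower. No peroxidase gene lay near a called region, but only 24 of all 8562 genes did. At that share none would be likely among 55 genes, so this says little about binding at peroxidase genes.

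**Figure D4:**
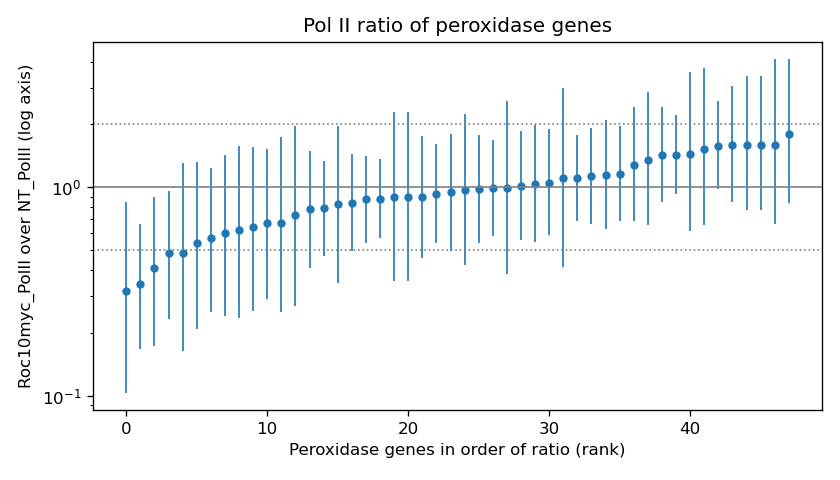
Pol II ratio, transgenic over nontransgenic (vertical log axis), with 95% counting intervals, for 48 peroxidase genes in order of ratio (horizontal axis, rank). The ratios run from 0.318 to 1.80.

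Of 14 monolignol biosynthesis genes, 13 had enough reads and 0 passed 2-fold in either direction. Their median ratio was 0.940, at the 40.005th percentile. The phenylalanine ammonia-lyase genes Os02t0626100-01, Os02t0626600-00 and Os05t0427400-00 had ratios of 0.933, 0.951 and 0.799, and each interval included 1. The caffeic acid O-methyltransferase gene Os08t0157500-01 had 0.940, the cinnamoyl-CoA reductase gene Os08t0277200-01 0.964 and the cinnamyl alcohol dehydrogenase gene Os02t0187800-01 1.08. The 4-coumarate-CoA ligase-like gene Os03t0132000-01 had 0.678 (0.464 to 0.986).

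In the HD-Zip IV family, to which Roc10 belongs, Os08t0187500-01, similar to Roc1, had a Pol II ratio of 1.43 (0.936 to 2.23) and an anti-myc ratio of 1.13 (0.734 to 1.71). Without its 1 region with a dinucleotide run, Os08t0187500-01 had a Pol II ratio of 1.61 (0.804 to 3.34) and an anti-myc ratio of 0.593 (0.257 to 1.26), with 10 anti-myc reads against 28. Os09t0526200-01, similar to ROC6, had a Pol II ratio of 1.80 (0.727 to 4.86). Os08t0136100-01, also similar to Roc1, held 9 Pol II reads against 5. The median of the 2 family genes with enough reads was at the 97.6th percentile, and at the 97.3rd, inside the middle 95%, with random lists matched on length as well. Os11t0484500-01, similar to 6-phosphogluconate dehydrogenase as is PGD1, had a Pol II ratio of 0.779 (0.538 to 1.12). No gene described as Roc10 is among those used here.

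The 11 other lists lay between the 9.80th and the 74.9th percentile. They were NAC, MYB and WRKY factors (9.80th), laccases and dirigent proteins (15.5th), histones (29.6th), photosynthesis (36.0th), guard cell terms (45.3rd), drought and ABA (46.7th), cell wall polysaccharide (55.4th), heat shock (56.4th), cuticle and lipid (62.1st), housekeeping (65.3rd) and ribosomal proteins (74.9th). With enough reads, guard cell terms held only 1 gene, photosynthesis 3, laccases and dirigent proteins 3 and histones 9, so their percentiles say little about those classes. Besides Os01t0705200-01 of the drought and ABA list, members past 2-fold were WRKY64 (Os12t0116700-01) at 0.450 (0.219 to 0.884), the ubiquitin ligase EL5 gene Os02t0178600-01 at 3.06 (1.08 to 10.6) and the RUB2 gene Os06t0650100-01 at 0.485 (0.234 to 0.963). The list taken by the keyword ribosomal protein held 2 such genes. Os04t0608100-01 was at 0.426 (0.170 to 0.989), and its description names a ribosomal protein S5 domain 2-type fold, which need not mean a ribosomal protein. Os03t0424800-00, similar to 40S ribosomal protein S19-3, was at 0.499916 (0.206 to 1.14), with 10 reads against 18. Scaled by median of ratios, Os06t0650100-01 was at 0.515 and Os03t0424800-00 at 0.531, no longer past 2-fold, and the xyloglucan fucosyltransferase gene Os04t0449200-01 moved from 1.94 to 2.06, past it. Of the 14 lists, 1 lay outside the middle 95% of random lists.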

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

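The tests with other pairings, without runs, high-copy regions or the transgenic anti-Pol II peaks, and with pooled reads were chosen after the data were seen, and the rest before. No paired analysis was possible because each group holds 1 library and no result comes from a test between conditions. A choice of the stronger peaks by the authors' score and a promoter of 2000 bp were not run, since the tables used here give no score and no strand.

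The Roc10-myc regions numbered 48. There were 994 at a ratio of at least 2 (1196 from counting error), 8 at 8 (2.60) and 1 with at least 30 reads (0.034). Against input there were 222 (8.07), and with pooled reads 24 (3.83). Without a minimum and with 1 read added to both libraries there were 97, and 13 had a lower limit of at least 2. By median of ratios there were 57 (29.3 from counting error).

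Pol II regions, 739 higher and 1480 lower, became 3512 and 6638 at 1.5-fold, 18 and 35 at 4-fold, 35 and 0 with at least 100 reads, 106 and 52 where the interval excludes 1.5-fold, 3816 and 8246 with input subtracted, and 186 and 358 with pooled reads. By median of ratios the lower regions numbered 985. Genes, 101 higher and 212 lower, became 470 and 917 at 1.5-fold, 3 and 4 at 4-fold, 3 and 0 with at least 100 reads, 10 and 3 by the interval, and 705 and 1501 with input subtracted. By median of ratios the lower genes numbered 126, and on the deposited lines 41 were higher and 108 lower. Other thresholds and minimums change counts by construction, and the cause was not tested for the rest.

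Pol II over input numbered 184 at 4-fold and 270 with pooled reads, against 1455. Anti-myc over input numbered 1800 at 2-fold, 85 without dinucleotide runs and 71 with pooled reads, against 199. Of the lists, 0 lay outside the middle 95% when matched on length as well, where the HD-Zip IV family moved to the 97.3th percentile and the other 13 stayed inside. On the deposited lines that family was at 47.8 and drought and ABA at 2.12. Called genes' Pol II percentile stayed inside the middle 95% at every setting run, from 10.4 to 80.5. The L1 box was at the 43.2nd percentile of shuffles in the 8 regions at 8-fold, and its short core at the 93.9th in the 48. A listed feature covered 35.4% of called regions and 2 of the 8 at 8-fold, and 76 in place of 77 peaks overlapped by 0.5 of the shorter. Without the peaks of the transgenic anti-Pol II library, 702 regions and 97 genes were higher and 1480 and 212 lower.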

Other observations

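The tests in this part were chosen after their results were seen, apart from that of the peaks of the untagged anti-myc library, which was set after the pattern and before its own result; a base composition test set before its result used regions of any length (median 1.01) and was replaced for that reason.

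Regions of up to 400 bp with a CA/GT or GA/TC run of at least 40 bp held a median of 1 input read and far more ChIP reads. Roc10-myc is argued against as the whole source, since anti-myc in the untagged plant was at a median of 38.5-fold over input in them, but tagged over untagged anti-myc was 2.01 there, beside 1.15 for Pol II, and a part of that size stays open. Pol II is argued against as well, since anti-Pol II over anti-myc had a median of 1.12 there, and base composition also, since 35 regions of up to 400 bp in the same GC range without runs or high copy had a median anti-myc over input of 1.57 (quartiles 0.916 and 2.33). DNA of another source in the ChIP libraries stays open. In both nontransgenic ChIP libraries, 98.7% of these regions were at least 4-fold over input. All are listed as peaks of the transgenic libraries, so they were not listed by those reads. Any background shared by the ChIP libraries, or few reads in the 1 input library, would give the same, so this test cannot single out that source. In regions over 400 bp the medians over input were 1.82 with CA/GT, 1.45 with GA/TC and 0.992 with AT runs, a smaller difference.

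The 35 regions with at least 100 reads and at least 2-fold higher Pol II in the transgenic plant included 34 of high copy, and 19 came from the peak list of that library and 9 from that of the tagged anti-myc library. More Pol II on them is argued against as the whole source, since the median anti-myc ratio between the genotypes was 1.68 in the 26 that are not tagged anti-myc peaks, and 1.69 and above 1 in 7 of 7 outside both lists. A larger share of some high-copy DNA in the transgenic libraries may explain the same 1.68. The 611 high-copy regions outside the anti-Pol II list had a median Pol II ratio of 0.968, so the pattern is not one of high-copy DNA as a whole. A difference between the plants themselves stays open, as untested.

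The 22 called regions in the peak list of the tagged anti-myc library have 3 candidate explanations. Extremes of counting may account for some, since Poisson counting gives 168 genome windows of 140 bp that pass the call. With at least 13 reads, as in 9 of the 22, it gives 1.13 windows of 140 bp or 6.88 of 171 bp. These numbers are for fixed windows side by side at a uniform density. Windows placed where reads lie would give more, so this stays open. For choice of peaks by the counts of 1 library, the mirror share of untagged anti-myc peaks at 4-fold was 0% of 36 (upper limit 9.74%), against 11.5% (7.36% to 16.9%), which met the condition set beforehand for arguing against it. That condition was then judged too weak, after its value was seen, because it left out the interval of the 11.5% and those peaks are longer, with a median of 1069 bp. Binding of Roc10 at its textbook site is argued against for most of the 22, since 0% of them held the L1 box (upper limit 15.4%). The short core of that box occurred in 3 of the 22 (13.6%, with an interval of 2.91% to 34.9%), the 92.6th percentile among shuffles. Choice of peaks and binding at other sites stay open.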
